A study of Mus musculus with 16 samples.

How the data were processed

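RNA was measured in 16 libraries of mouse embryonic skin taken at embryonic day 14.5 and separated into 8 cell fractions by fluorescence-activated cell sorting. Each fraction had 2 libraries. The labels give the fractions as Pc, Epi, DC, Fb, DCSch, Sch, Mc and Neg, and give replicate numbers 1 and 2 within each. The labels do not spell these names out. They are read here, from general knowledge of the study, as placode, epidermis, dermal condensate, fibroblast, dermal condensate with Schwann cells, Schwann cell, melanocyte and the negative fraction. The markers used for sorting are not given in the sources used here, so a gene that served for sorting is no finding of its own. Per the labels' protocols, RNA with an integrity number of at least 8.8 was used, 6 ng of it was reverse transcribed and amplified to cDNA with a NuGEN kit, and 100 ng of cDNA went into each of 16 barcoded libraries. No label says that the replicates came from separate litters or embryos, so the p-values measure only the spread between these samples, technical spread included.

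The authors deposited 1 table of FPKM values, fragments scaled by transcript length and by the fragments of the library, with 23235 rows and a column for each library. Per the submitters' processing notes, the tools were TopHat2 2.0.3, Bowtie2 and Cufflinks 2.1.1 on the mm10 genome build, with no role or setting given for each. Plain FPKM values are relative to the fragments of their own library, so a fraction in which a few genes take many fragments has lower values for the rest. Whether the deposited values were also scaled between libraries is not stated, so this may not hold for them. The file gives no counts. Exact zeros were treated with care, because 10 abundant genes are listed at 0 in some libraries and above 20 FPKM in at least 14 others. One of them is Malat1, a long nuclear RNA, which is listed at 0 in both DC libraries. No fold is given for it. The other 9 are Mir, Snora or Scarna genes. A locus in the file can span a neighbouring gene, as for Pmel, Shh and Ptx3, and 434 rows that share a symbol with another row were tested but not named. Gene positions are those of the file, written 1-based on mm10.

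All values were moved to log2(FPKM + 1), with a pseudocount of 1. Differences on this scale understate the change of genes with low FPKM. The 14171 rows with an FPKM of at least 1 in at least 2 libraries were fitted with limma 3.58.1 in R 4.3.3. The model had 1 mean per fraction over all 16 libraries, with a trended and robust estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 with an absolute log2 difference of at least 1. The comparisons were Pc with Epi, DC with Fb, Mc with Sch, and DC, Sch and DCSch with each other. A signature gene of a fraction was higher than each of the other 6 fractions, DCSch left aside, with the largest of the 6 p-values adjusted over genes and every log2 difference at least 1. The position of DCSch between DC and Sch was the median over genes of (DCSch - Sch) / (DC - Sch) in FPKM. It used genes called between DC and Sch with an absolute log2 difference of at least 2 and at least 5 FPKM in the higher fraction.

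Gene lists for cell types, signalling pathways and processes were fixed from general knowledge before the data were examined, 33 in all with 545 entries, of which 538 were found in the table. Foxm1, Flg, Zeb2, Hba-a2, Hbb-b2 and Hbb-bt had no row of that name. Older symbols were matched for Emr1, Sfpi1 and Beta-s. Hba-a1 shares its symbol between rows and was left out of the list. Several dermal condensate genes on the list became known as markers partly through work on these samples, so that list is not independent evidence. Lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01 and again with the correlation estimated, and with fry. The rule for naming genes was also fixed before the data were examined. It takes up to 8 higher and 8 lower genes by the largest log2 difference among called genes with at least 10 FPKM in the higher fraction, without overlap of the libraries. It adds up to 4 called members per list, any further member whose value is given, and a set of fixed genes per comparison. For each signature it takes the 5 genes with the largest smallest difference.

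Whether the replicate numbers pair the samples was checked from the data. The deviations of same-numbered libraries from their fraction means went together in all 28 pairs of fractions, with correlations across genes from 0.148 to 0.656 and a median of 0.491. The numbers were therefore read as pairing the samples. The model without a replicate term, fixed beforehand, is the main one, and the one with it is given where it changes a call or moves a count by over 1.5 times. The depth of the libraries is not stated. Below 0.3 FPKM the values fall on steps of single fragments, which gave the relative depth of the replicate 2 libraries, clear in all 28 pairs. Against Sch, depth was 1.17 times in Fb, 1.22 in DCSch, 1.27 in Neg, 1.49 in DC, 2.14 in Pc, 2.6 in Epi and 3.75 in Mc. Any scaling between libraries in the deposited values would be part of these figures. Within replicate 1 the steps were clear in 4 of 28 pairs and between replicates in 0 of 64, so no other relative depth is given, and absolute depth stays unknown.

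The calls, the signatures, camera, the position and the mixture weights were tested on simulated data, and the other procedures were not. With 100 genes changed at each size among 14053 simulated genes, the Pc with Epi comparison recovered 64 at a log2 change of 1.5 and 91 at 3, with 0 of 13853 unchanged genes called. With the replicate term it recovered 92 and 96 of 100, with 3 of 13843 unchanged genes called. Each gene's simulated replicate shift was the same in all fractions, as that term assumes, so its gain is built in. Changed genes, here and for the signature, had a mean of at least 5 FPKM over the libraries. Recovery at lower levels was not simulated. The Mc signature procedure on 13046 simulated genes recovered 40 and 92 of 100, with 0 of 12846 unchanged genes called. A mixture made at position 0.4 gave 0.403, and a mixture with an Fb weight of 0.2 gave 0.206. The alternatives tried were pseudocount, filter, scaling, variance model, replicate term, each library left out in turn, only the libraries compared, comparator fractions, gene cut-offs of the position, and the correlation in list tests. A replicate term with a correction for GC content was added after seeing the data. GC content came from the GENCODE M21 transcripts of the same build and covered 93.7% of the tested genes. Mixture weights were fitted with SciPy 1.17.1 under Python 3.11.15.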

Results

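The data were FPKM values of 8 sorted cell fractions of embryonic mouse skin at day 14.5, each in 2 libraries. At this stage hair follicles begin to form: the epidermis thickens into placodes, and fibroblasts gather beneath them into dermal condensates. Values below are means ± SD of the 2 libraries of a fraction. The FPKM of a library summed to between 439201 (Sch replicate 1) and 606437 (Epi replicate 1), and 11273 to 12137 genes reached 1 FPKM. Replicates of a fraction correlated across genes at Pearson's r of 0.939 (Fb) to 0.979 (Epi) on the log2 scale, genes not being independent. The first principal component held 38.2% of the variance and placed Pc, Epi and Mc on one side and the other fractions on the opposite side. Rescaling every library to the same total, in place of the deposited scale, moved the median log2 difference of all genes, within 0.03 of 0 as deposited, to 0.11 for Pc against Epi, -0.17 for Mc against Sch, -0.12 for DC against Sch and -0.11 for DCSch against Sch.

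Each fraction named for a single cell type stood highest in the gene list of that type, with keratinocyte genes shared by Pc and Epi. Keratins Krt5 and Krt14 of the basal epidermis reached 1392 ± 362 and 951 ± 305 FPKM in Pc and 1229 ± 178 and 775 ± 173 in Epi, and the keratinocyte list had its highest mean level in Epi, 3.49 log2 units above the mean of the fractions, and 3.36 in Pc. The placode list was highest in Pc (2.02), the epidermal differentiation list in Epi (3.12), the fibroblast list in Fb (2.79), the dermal condensate list in DC (3.60), the Schwann cell list in Sch (3.21) and the melanocyte list in Mc (5.09). Neural crest transcription factors were highest in Sch (2.00), next in Mc (1.32), the 2 fractions whose cell types descend from the neural crest. The neuron list was also highest in Sch (0.98). Of the Merkel cell list only Krt18 was tested, at 1.31 ± 0.721 FPKM in Pc and 1.31 ± 1.18 in Epi.

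**Figure D1:**
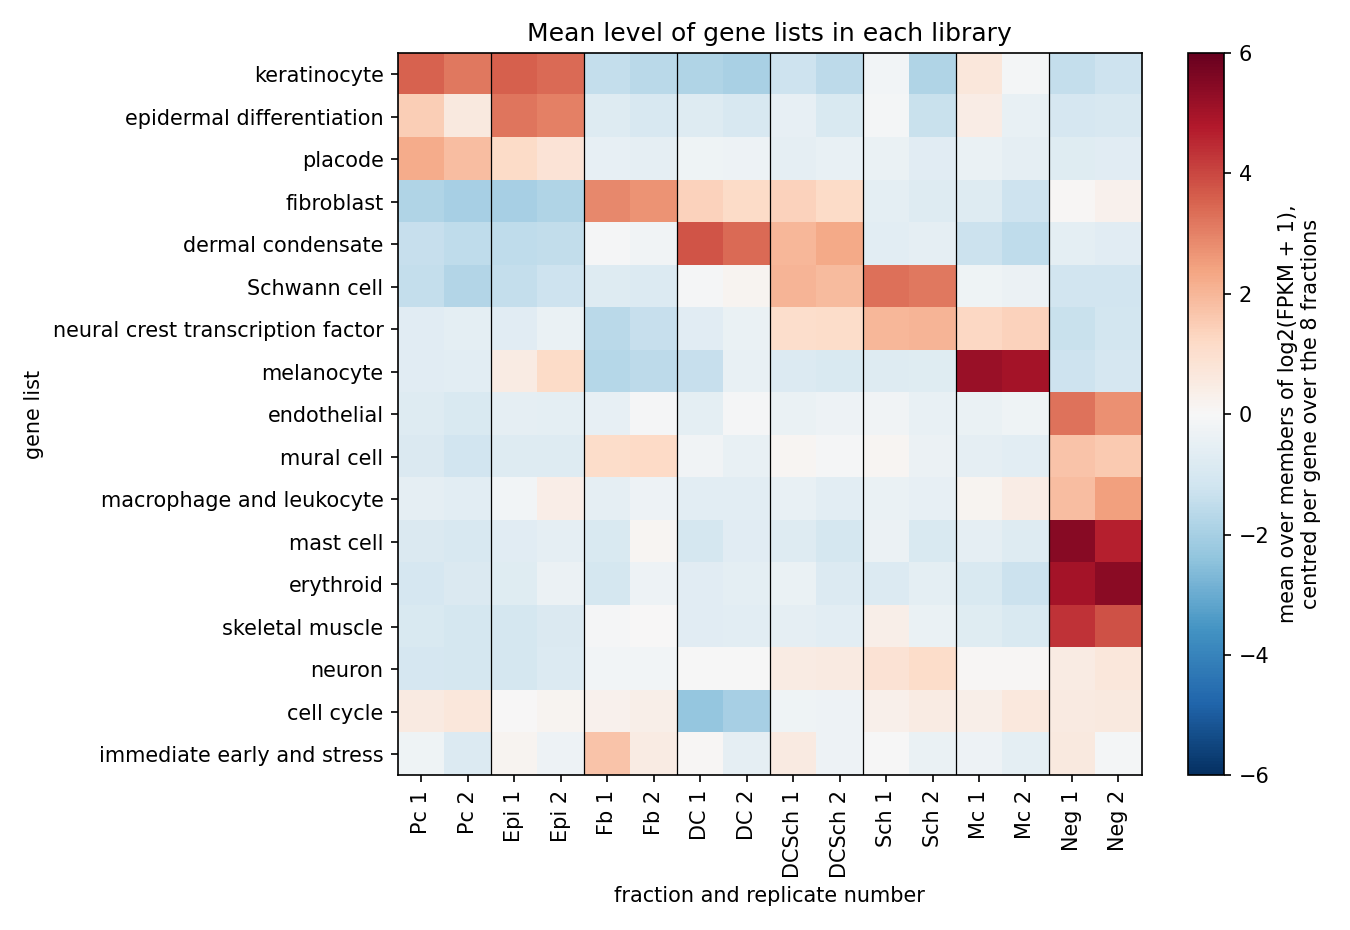
Mean level of 17 gene lists (rows) in each of the 16 libraries (columns, by fraction and replicate number). The colour gives the mean over list members of log2(FPKM + 1) centred per gene over the 8 fractions. The erythroid list stands at 5.19 in Neg, the melanocyte list at 5.09 in Mc and the cell cycle list at -2.16 in DC, on average over the 2 libraries.

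Signature genes, higher in 1 fraction than in each of the other 6 with DCSch left aside, numbered 482 in Neg, 346 in DC, 277 in Sch, 215 in Fb, 164 in Mc, 112 in Epi and 1 in Pc. With a replicate term Pc had 6. The Pc gene was Dkk4, an inhibitor of Wnt signalling (chromosome 8, 22624043 to 22627546). The Epi signature was led by Bpifc (41.7 ± 2.70 FPKM), Ly6g6c (18.0 ± 5.93), the desmosomal cadherin Dsc1 (16.3 ± 1.53), Sdr16c6 (17.9 ± 1.45) and the phospholipase Pla2g2f (23.9 ± 6.71). It fell to 44 genes without Pc replicate 2, 53 without Epi replicate 2 and 56 without Epi replicate 1. Leading DC genes were Bmp3 (199 ± 35.9), the neuropeptide gene Gal (203 ± 93.3), the transcription factor Foxd1 (176 ± 105), Trim9 (97.1 ± 3.31) and Smoc1 (138 ± 39.6). Fb was marked by Vcam1 (236 ± 55.9), the angiotensin receptor Agtr2 (429.6 ± 189), and the matrix genes Dpt (237 ± 10.8) and Thbs2 (80.6 ± 6.14). In Mc the leading genes were Ptgds (1465 ± 275), Mlana (747 ± 102), Mcoln3 (188 ± 10.1), Slc45a2 (161 ± 0.993) and Pmel (1346 ± 273), and in Sch they were Gpr17 (192 ± 24.2), the fatty acid binding protein gene Fabp7 (1267 ± 249), Gfra3 (203 ± 24.9), Col20a1 (70.0 ± 27.0) and Moxd1 (302 ± 39.1).

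The Neg fraction carried the genes of cell types that none of the other fractions is named for. The embryonic globins Hbb-y (24725 ± 3565 FPKM) and Hba-x (8687 ± 1576), the adult globins Hbb-b1 (6456 ± 2639.9) and Beta-s (10059.9 ± 3323), and the mast cell carboxypeptidase Cpa3 (754 ± 214) led its signature. Hemoglobin genes took 8.38% and 10.3% of the FPKM of the 2 Neg libraries and 0.0267% to 0.0746% in the other 14. All 6 tested mast cell genes, 8 of 9 erythroid, 15 of 17 endothelial, 12 of 14 skeletal muscle, 7 of 13 macrophage and leukocyte and 1 of 9 mural cell genes were Neg signature genes. Among them were the endothelial Pecam1 (63.8 ± 10.7 FPKM), the muscle regulator Myf5 (11.9 ± 3.72) and the tryptase gene Tpsb2 (77.9 ± 53.6).

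Few genes were called between Pc and Epi, the epithelial pair. Pc was higher in 22 genes and lower in 194, of 14171 tested. Placode genes were higher in Pc: Dkk4 measured 19.1 ± 1.37 FPKM against 4.16 ± 0.545 in Epi, Fgf20, an early placode signal, 3.76 ± 0.239 against 0.873 ± 0.607, and Edar, the ectodysplasin receptor, 13.7 ± 0.197 against 5.53 ± 1.01. Genes of epidermal stratification were lower in Pc. Dsc1 measured 1.26 ± 0.542 FPKM against 16.3 ± 1.53, and suprabasin, Sbsn, 29.5 ± 20.7 against 194 ± 3.82. The log2 differences were 1.96 for Dkk4 (SE 0.18, limma adjusted p = 0.000346), 1.38 for Fgf20 (SE 0.19, limma adjusted p = 0.00339), 1.18 for Edar (SE 0.19, limma adjusted p = 0.00967) and -2.96 for Dsc1 (SE 0.23, limma adjusted p = 0.000180). With a replicate term Pc was higher in 59 genes and lower in 309, and these included all 22 and 194.

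Of 16 placode genes, 4 were higher in Pc (Dkk4, Fgf20, Edar, Shh) and 12 were not called. There were 10 adjusted over the list alone and 8 with a replicate term. The list rose as a set (camera adjusted p = 2.17e-18, and adjusted p = 0.0201 with an estimated correlation). The adjusted p was 0.0567 with a replicate term and an estimated correlation. Shh, the hedgehog ligand, was low in both, 1.99 ± 0.927 FPKM in Pc and 0.360 ± 0.444 in Epi, at a locus that the file draws wide (chromosome 5, 28456840 to 28719209). Lhx2, a stem cell transcription factor, measured 1.66 ± 0.865 and 0.185 ± 0.261 (limma adjusted p = 0.139, and 0.0352 with a replicate term, which called it). Wnt10b (33.4 ± 11.8 and 15.5 ± 5.38) and Lef1 (87.0 ± 3.13 and 52.4 ± 3.02) were not called in either model. The EDA and NF-kB list had 1 of 13 members higher, Edar, or 4 adjusted over the list alone and 4 with a replicate term (camera adjusted p = 1.64e-07, and adjusted p = 0.0378 with an estimated correlation). The FGF response list had 1 of 10 higher, the phosphatase gene Dusp6 (21.6 ± 1.03 against 10.1 ± 1.05 FPKM), or 2 with a replicate term (camera adjusted p = 2.05e-05, and adjusted p = 0.0219 with an estimated correlation). For both lists the adjusted p was 0.0567 with a replicate term and an estimated correlation. Aurka (39.9 ± 3.22 against 15.8 ± 0.302 FPKM) and Ube2c (296 ± 13.7 against 142 ± 21.0), which act in mitosis, were the 2 of 33 cell cycle genes higher in Pc, or 4 adjusted over the list alone and 7 with a replicate term. The list's camera adjusted p was 3.22e-09, and adjusted p = 0.103 with an estimated correlation. Prc1 and Cdc25c, also mitotic, the hyaluronan synthase Has3, the fibronectin gene Fn1 and Mybpc1 were higher as well, with log2 differences of 1.20, 1.15, 1.40, 1.12 and 1.33.

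**Figure D2:**
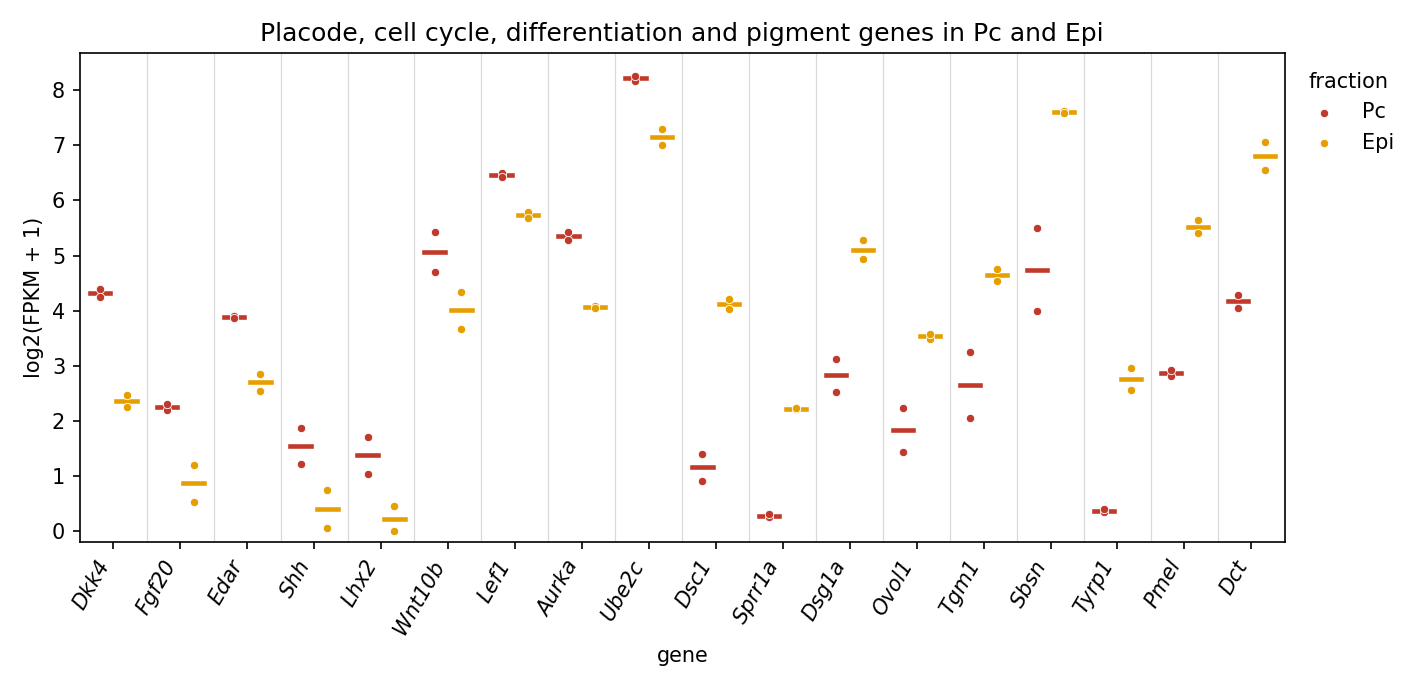
FPKM of 18 genes in the Pc and Epi libraries, as log2(FPKM + 1) on the vertical axis. Points are the 2 libraries of a fraction and bars their mean on that scale. Both Pc libraries lie above both Epi libraries for Dkk4, Fgf20 and Edar and below them for the 6 epidermal differentiation genes.

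Of 14 epidermal differentiation genes, 6 were lower in Pc (Dsc1, Sprr1a, Dsg1a, Ovol1, Tgm1, Sbsn) and none higher, or 12 adjusted over the list alone and 11 with a replicate term. The list fell as a set (camera adjusted p = 1.36e-23, and adjusted p = 0.0493 with an estimated correlation, 0.0567 with a replicate term too). Tgm1, the transglutaminase of the cornified envelope, measured 5.84 ± 3.79 FPKM in Pc and 24.2 ± 2.73 in Epi. Ly6g6c, Fam25c, Bpifc, Sdr16c6, Pla2g2f and Ly6d were the other leading genes that were lower, with log2 differences from -2.70 (Ly6d) to -3.54 (Ly6g6c). None of 18 keratinocyte genes was called, with 1 lower adjusted over the list alone and 1 with a replicate term. Cdkn1a, a cell cycle inhibitor, was lower in Pc (5.21 ± 1.53 against 24.5 ± 6.34 FPKM), 1 of 6 CDK inhibitor genes and also 1 of 22 dermal condensate genes. Melanocyte genes were lower in Pc too, 6 of 16 (Tyrp1, Pmel, Gpnmb, Mlana, Dct, Ednrb), or 11 adjusted over the list alone and 11 with a replicate term. The camera adjusted p was 2.02e-20, and adjusted p = 0.0577 with an estimated correlation. Dct, which makes pigment precursors, measured 17.0 ± 1.97 FPKM in Pc, 112 ± 27.8 in Epi and 2965 ± 789 in Mc. With libraries rescaled to the same total 2 of the 6 kept the call and with quantile normalization 5, while the list's median log2 difference of -1.48 became -1.49 and -1.37. The macrophage and leukocyte list had 1 of 13 lower, Tyrobp (0.763 ± 0.258 against 5.03 ± 0.767 FPKM), or 3 adjusted over the list alone and 2 with a replicate term (camera adjusted p = 4.49e-06, and adjusted p = 0.124 with an estimated correlation). Single members were called in the hedgehog (Shh), FGF ligand (Fgf20), Wnt inhibitor and Wnt target lists (Dkk4), all higher, and in the fibroblast (Fn1 higher, Dpp4 lower), Schwann cell (L1cam lower) and immediate early and stress lists (Zfp36 lower, or 3 genes with a replicate term). The hedgehog list rose as a set (camera adjusted p = 0.000373, and adjusted p = 0.141 with an estimated correlation), as did Wnt ligands (0.00543, and adjusted p = 0.291 with an estimated correlation) and Hox genes (0.00543, and adjusted p = 0.425 with an estimated correlation). Axon guidance genes (0.0275, and adjusted p = 0.114 with an estimated correlation), Wnt targets (0.0275, and adjusted p = 0.357 with an estimated correlation), Wnt inhibitors (0.0430, and adjusted p = 0.290 with an estimated correlation) and BMP ligands and antagonists (0.0430, and adjusted p = 0.138 with an estimated correlation) rose by camera too. Immediate early and stress (0.0430, and adjusted p = 0.676 with an estimated correlation), endothelial (0.0430, and adjusted p = 0.568 with an estimated correlation) and Schwann cell genes (0.0458, and adjusted p = 0.365 with an estimated correlation) fell. Under a replicate term the camera adjusted p was 0.0957 for Wnt targets, 0.199 for Wnt inhibitors, 0.0614 for BMP ligands and antagonists, 0.0614 for endothelial and 0.0957 for Schwann cell genes. No member was called among the endothelial, mural cell, mast cell, erythroid, skeletal muscle, neuron, neural crest transcription factor, Wnt ligand, BMP ligand and antagonist, BMP target, Notch, TGF-beta and activin, axon guidance, collagen and Hox lists. With a replicate term Bmp2, Wif1 and Trps1 were higher and Notch3 lower. Adjusted over the list alone there were 2 Wnt inhibitors higher and 1 mural cell gene lower, and the other counts did not change. The median and mean log2 difference had opposite signs for keratinocyte (0.27 and -0.13), fibroblast (-0.02 and 0.01), FGF ligand (-0.06 and 0.11) and CDK inhibitor genes (0.12 and -0.26), and the BMP target median was 0.26 with a mean just below 0. Of the 17 lists camera called, fry called 6 (epidermal differentiation, placode, melanocyte, FGF response, EDA and NF-kB, cell cycle), and no other list. The count of 216 depended on single libraries: it was 67 without Pc replicate 2, 79 without Epi replicate 2 and 107 without Epi replicate 1. The 22 genes higher in Pc became 8, 5 and 9 in these, and 7 without Pc replicate 1. Of the 35 called genes that lead the ranking, were fixed beforehand or belong to a list, Dkk4, Fgf20, Bpifc, Dsc1, Ly6d, Ly6g6c, Sdr16c6, Sprr1a and Tyrp1 kept the call whichever library was left out, and the other 26, Edar, Shh, Tgm1 and Sbsn among them, did not. Aurka, Cdc25c, Dct, Dusp6, Ednrb, Has3, Mybpc1, Prc1, Ube2c and Zfp36 lost it in all 4 fits with a library left out. With a pseudocount of 0.1, or with only the 4 libraries compared, no gene was called higher in Pc. Dkk4 and Fgf20 thus lost the call in both settings.

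DC and Fb, the dermal pair, differed in 2172 genes, 868 higher in DC and 1304 lower. Transcription factor and signalling genes of the condensate were far higher in DC. Sox2, at a locus that the file draws wide (chromosome 3, 34560381 to 34677993), measured 22.2 ± 4.04 FPKM against 0.0278 ± 0.0394 in Fb. Sox18 measured 829.6 ± 683 against 2.73 ± 0.590, and Bmp4, a secreted growth factor, 457 ± 117 against 22.3 ± 4.91. Genes of cell division were lower in DC. Birc5, also called survivin, measured 15.2 ± 0.516 FPKM against 174 ± 24.3, and Bub1b, of the spindle checkpoint, 3.52 ± 0.907 against 42.9 ± 2.89. The matrix genes Dpt (3.87 ± 0.319 against 237 ± 10.8) and the collagen crosslinking enzyme gene Lox (3.30 ± 1.11 against 145 ± 9.89) were lower as well. The log2 differences were 4.49 for Sox2 (SE 0.19, limma adjusted p = 1.27e-07), 7.51 for Sox18 (SE 0.65, limma adjusted p = 8.17e-06), -3.42 for Birc5 (SE 0.16, limma adjusted p = 1.92e-07) and -5.61 for Dpt (SE 0.30, limma adjusted p = 3.72e-07).

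Of 22 dermal condensate genes 20 were higher in DC and none lower, also adjusted over the list alone, which is not independent evidence since some of them were described with these samples. The camera adjusted p was 1.83e-20, adjusted p = 0.0165 with an estimated correlation and 0.0969 with a replicate term too. Nog and Alpl, not called, measured 0.145 ± 0.0433 and 0.674 ± 0.713 FPKM in DC. Prdm1 measured 288 ± 63.7 FPKM against 9.24 ± 1.01 in Fb, Cdkn1a 535 ± 238 against 13.4 ± 5.77, and Trps1 75.8 ± 34.6 against 5.32 ± 1.97. The hedgehog list split. The pathway's targets Ptch1 (311 ± 24.5 against 31.2 ± 10.3), Gli1 (122 ± 44.4 against 25.2 ± 17.0) and Hhip were among 4 that were higher. Gli3, Disp1 and the co-receptors Cdon and Gas1 were lower, and 4 of 12 were not called. Gli1 lost the call without DC replicate 1 and without Fb replicate 2. Leading genes outside the lists were Vat1l, Pdlim3, Grin2a, a glutamate receptor gene, and Lynx1, with log2 differences of 5.83, 5.50, 5.43 and 5.24. Gal and Foxd1 reached 7.28 and 6.49. In the Notch list 4 of 17 were higher (Dll1, Heyl, Hes5, Hey1) and 3 lower (Jag1, Notch2, Hes1). The ligand gene Dll1 measured 66.6 ± 12.2 FPKM against 0.332 ± 0.135. Among BMP ligands and antagonists 4 of 16 were higher (Bmp4, Bmp3, Bmp7, Fst) and 5 lower, among them the antagonist gene Grem1 (0.445 ± 0.0481 against 15.8 ± 1.27). Of 6 BMP targets Smad7 was higher and Id2 lower. FGF ligands had 2 of 13 higher and 5 lower, with Fgf10 at 92.3 ± 32.9 against 6.51 ± 1.73 FPKM and Fgf18 at 0.675 ± 0.162 against 9.30 ± 1.24. FGF response genes had 4 of 10 higher (Il17rd, Spry1, Dusp6, Spred1) and Spry2 lower (camera adjusted p = 0.0126, and adjusted p = 0.151 with an estimated correlation).

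Of 33 cell cycle genes 29 were lower in DC and none higher, or 30 adjusted over the list alone and 30 with a replicate term. The camera adjusted p was 7.31e-25, adjusted p = 0.0176 with an estimated correlation and 0.0969 with a replicate term too. The median log2 difference of the list was -2.69. Mcm2, Mcm6, Mcm7, of the replicative helicase, and E2f1 were not called, with log2 differences of -0.93, -0.88, -0.45 and -1.19. Of 6 CDK inhibitor genes Cdkn1a and Cdkn1c were higher, Cdkn1c at 1532 ± 534 FPKM against 408 ± 139.9, and Cdkn2c was lower (2.15 ± 0.0534 against 22.8 ± 0.297). Against Sch, DC was lower in 31 of the same 33 cell cycle genes. The list's mean level in DC, -2.16, was the lowest of the 8 fractions.

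**Figure D3:**
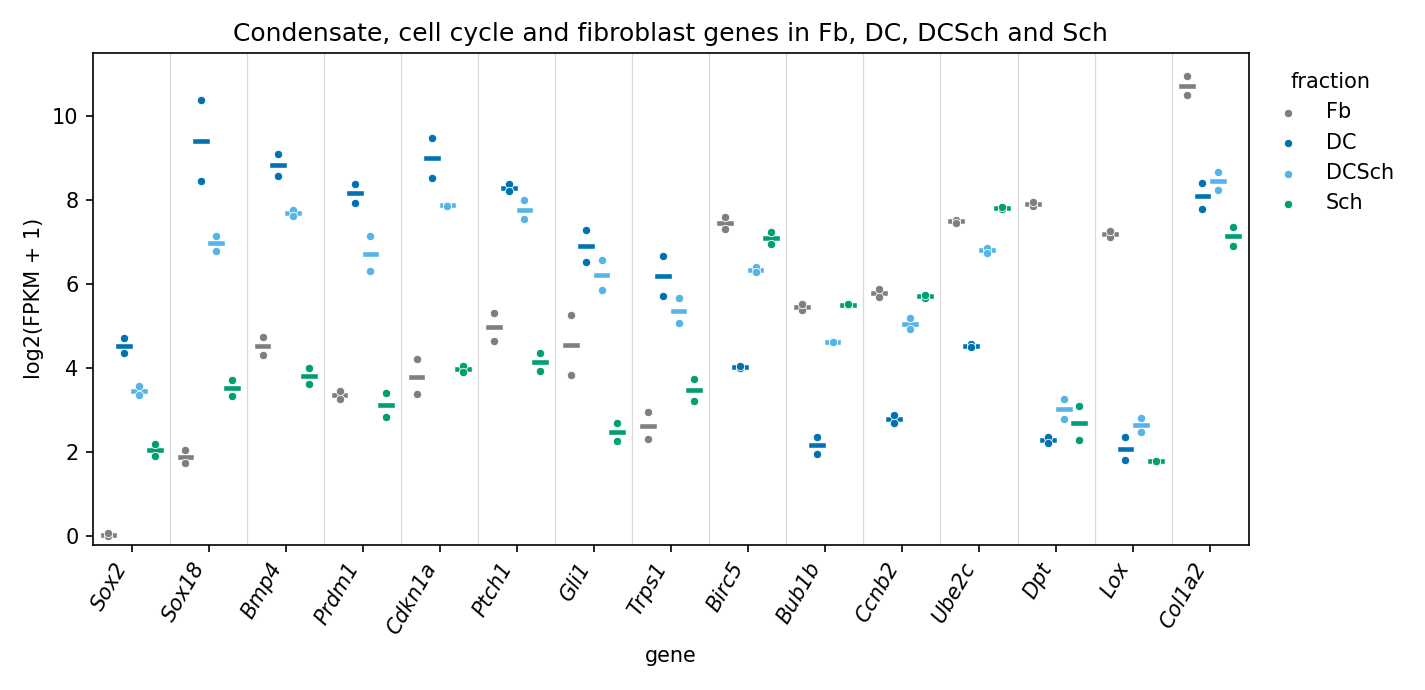
FPKM of 15 genes in the Fb, DC, DCSch and Sch libraries, as log2(FPKM + 1) on the vertical axis. Points are the 2 libraries of a fraction and bars their mean on that scale. The 4 cell cycle genes Birc5, Bub1b, Ccnb2 and Ube2c are lowest in DC, and the 8 condensate genes from Sox2 to Trps1 highest.

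Of 20 fibroblast genes 12 were lower in DC and Thy1 higher (camera adjusted p = 6.09e-05, and adjusted p = 0.222 with an estimated correlation). Col1a2 measured 276 ± 82.9 FPKM in DC and 1695 ± 378 in Fb, and decorin, Dcn, 174 ± 15.1 and 1282 ± 306. Pdgfra, a receptor gene of dermal cells, was not called (91.6 ± 13.9 and 132 ± 23.4). Agtr2, Islr, Ptn, Thbs2 and Ptx3 were the other leading genes that were lower, with log2 differences from -5.60 (Agtr2) to -4.86 (Thbs2). Malat1 is listed at 0 in both DC libraries and at 2101 and 3102 FPKM in Fb. Of 24 collagens 7 were lower and 4 higher (Col23a1, Col15a1, Col7a1, Col4a1), or 8 and 5 adjusted over the list alone. Col12a1 measured 24.7 ± 3.13 against 222 ± 22.3 FPKM, and Col23a1 233 ± 42.2 against 22.8 ± 1.89. Wnt ligands had 4 of 16 lower (Wnt2b, Wnt2, Wnt4, Wnt11) and none higher. Wnt inhibitors had 5 of 18 lower, Sfrp1 among them (6.39 ± 1.04 against 46.7 ± 6.16), and 2 higher, Frzb (44.8 ± 0.263 against 0.727 ± 0.211) and Wif1. Wnt targets had Lef1 and Nkd1 higher and Lgr5 and Sp5 lower, of 14. The TGF-beta and activin list had 2 of 16 higher (Ltbp1, Inhba) and 4 lower, the axon guidance list 2 of 20 higher (Sema6a, Efna4) and 6 lower (Ntn1 at 3.46 ± 2.05 against 48.5 ± 17.9), the Hox list 1 of 31 higher and 4 lower, the EDA and NF-kB list 1 of 13 each way, and the placode list 3 of 16 higher (Lef1, Sox9, Tnfrsf19) and Cdh3 lower. Of 16 immediate early and stress genes, which answer to stimuli and to tissue handling, 7 were lower in DC, or 9 adjusted over the list alone and 10 with a replicate term. Fos measured 6.14 ± 2.29 against 40.2 ± 22.0 FPKM and lost the call without DC replicate 2 and without Fb replicate 1 (list camera adjusted p = 0.000622, and adjusted p = 0.787 with an estimated correlation). The list's mean level was 1.73 in Fb replicate 1 and 0.50 in Fb replicate 2. Genes of other cell types moved too. Of 9 mural cell genes 4 were lower (Abcc9, Kcnj8, Acta2, Tagln; camera adjusted p = 0.00462, and adjusted p = 0.218 with an estimated correlation), and 3 of 14 skeletal muscle genes and Lyz2 of 13 macrophage and leukocyte genes were lower. Tagln, Lyz2 and Myog, of muscle, lost the call in 3 of the 4 fits with a library left out. Of 15 Schwann cell genes 7 were higher in DC, Ngfr (326 ± 167 against 43.3 ± 13.1) and Fabp7 (47.0 ± 32.6 against 6.79 ± 3.94) among them, and 2 lower (camera adjusted p = 0.00959, and adjusted p = 0.323 with an estimated correlation). Neural crest transcription factors had 5 of 10 higher, Tfap2a and Sox9 among them, and Snai2 lower (camera adjusted p = 0.0226, and adjusted p = 0.322 with an estimated correlation, 0.0645 with a replicate term). The melanocyte list had Ednrb (63.5 ± 17.3 against 1.58 ± 0.916) and Pmel higher of 16 (camera adjusted p = 0.0381, and adjusted p = 0.879 with an estimated correlation, 0.0784 with a replicate term). Its mean level was -1.38 in DC replicate 1 and -0.45 in DC replicate 2, against -1.69 and -1.58 in Fb. Flt1 and Kdr were higher and Tek lower among 17 endothelial genes, and Tubb3 was higher among 7 neuron genes. Klf4 was higher among 14 epidermal differentiation genes, and no keratinocyte, mast cell or erythroid gene was called. Adjusted over the list alone, 5 hedgehog and 5 FGF response genes were higher, 2 BMP targets, 5 Hox genes and 0 macrophage and leukocyte genes lower, and the lists without a count of their own did not change. A replicate term gave 2 BMP targets lower. The median and mean log2 difference had opposite signs for BMP ligands and antagonists (-0.25 and 0.10), Wnt targets (0.12 and -0.02), TGF-beta and activin (0.04 and -0.17) and CDK inhibitor genes (-0.10 and 0.55). For epidermal differentiation genes and BMP targets both were below 0 while camera and fry pointed up, for endothelial genes fry alone did, and for hedgehog genes with a mean above 0 fry pointed down. Camera called none of these as a set. Of the 9 lists camera called, fry called 8, all but the melanocyte list. It also called 7 that camera did not: Notch and placode upward, and Wnt ligand, FGF ligand, BMP ligand and antagonist, TGF-beta and activin and skeletal muscle downward, of which all but Wnt ligand and skeletal muscle had called members both ways. Of 186 called genes that lead the ranking, were fixed beforehand or belong to a list, 140 kept the call whichever library was left out. Among the 46 that did not were, besides those given above, Col4a1, Col7a1, Disp1, Dusp6, Efna4, Fabp7, Fst, Hes1, Jag1, Nkd1, Notch2, Pmel, Spred1, Tek, Wif1 and Wnt11.

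Mc and Sch, the pair of neural crest descent, differed in 1678 genes, 642 higher in Mc and 1036 lower. Pigment genes rose to very high levels in Mc. Dct (chromosome 14, 118012790 to 118052246) measured 2965 ± 789 FPKM against 4.49 ± 0.684 in Sch, Pmel, the fibril protein of pigment granules, 1346 ± 273 against 2.53 ± 0.0288, and Mitf, the regulator of the lineage, 141 ± 37.3 against 1.71 ± 0.265. Glial genes were higher in Sch. Fabp7 measured 49.1 ± 9.80 FPKM in Mc against 1267 ± 249, and Gfra3, a receptor gene of the GDNF family, 0.769 ± 0.00655 against 203 ± 24.9. Sox10, a regulator of both lineages, was alike within the spread of the libraries at 127 ± 5.89 in Mc and 139.9 ± 67.4 in Sch (log2 difference -0.05, SE 0.38, limma adjusted p = 0.971). The log2 differences were 9.06 for Dct (SE 0.52, limma adjusted p = 3.00e-07), 5.69 for Mitf (SE 0.36, limma adjusted p = 5.90e-07) and -4.66 for Fabp7 (SE 0.56, limma adjusted p = 9.30e-05).

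Of 16 melanocyte genes 14 were higher in Mc, with Ednrb and Rab38 not called (camera adjusted p = 7.60e-26, and adjusted p = 0.0741 with an estimated correlation). Kit, a growth factor receptor gene, measured 456 ± 92.8 FPKM against 7.88 ± 0.543, and Tyrp1 174 ± 57.1 against 0.333 ± 0.142. Ptgds, Mlana, Gpnmb, Slc45a2 and Mcoln3 were the other leading genes, with log2 differences from 6.99 (Mcoln3) to 9.23 (Ptgds). Of 15 Schwann cell genes 14 were lower in Mc and Egr2 was not called (camera adjusted p = 2.28e-16, adjusted p = 0.0145 with an estimated correlation and 0.0850 with a replicate term too). The neuregulin receptor gene Erbb3 measured 38.6 ± 1.13 FPKM against 80.4 ± 15.1. Erbb3 kept the call only without Sch replicate 2. Gpr17, Gfra3, Moxd1, Gap43, Adam23, Cdh6, Pcdh20 and Vat1l led the genes higher in Sch, with log2 differences from -6.01 (Vat1l) to -7.07 (Gpr17). Gap43, a growth cone gene, reached 468 ± 52.3 FPKM. Neural crest transcription factors had 3 of 10 higher in Mc, Tfap2a, Pax3 and Ets1, and 4 lower, Sox8, Sox5, Foxd3 and Sox9. No left-out fit kept Pax3 or Ets1. With libraries rescaled to the same total 1 was higher and 4 lower, and with quantile normalization 3 and 4. Foxd3 measured 15.4 ± 9.53 against 96.7 ± 25.1 FPKM.

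**Figure D4:**
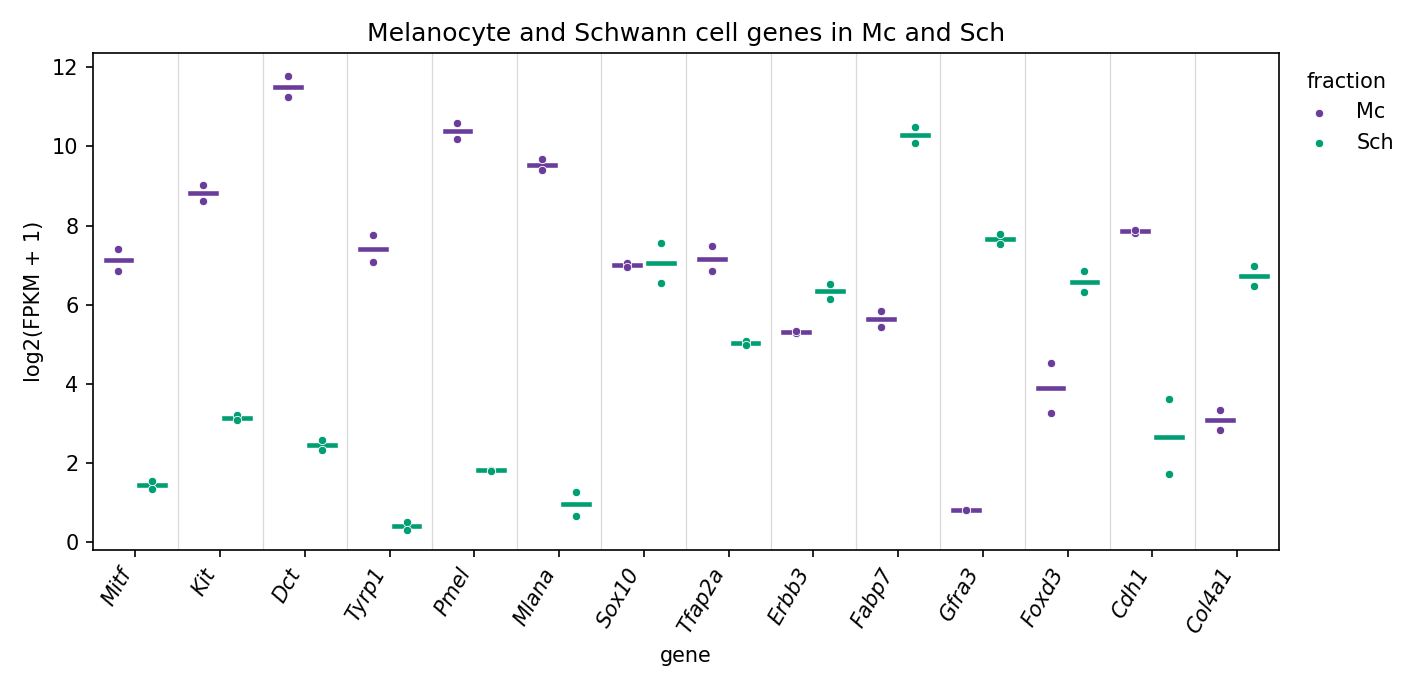
FPKM of 14 genes in the Mc and Sch libraries, as log2(FPKM + 1) on the vertical axis. Points are the 2 libraries of a fraction and bars their mean on that scale. Pigment genes lie far above in Mc, glial genes in Sch, and the Sox10 libraries of the fractions overlap.

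Of 24 collagens 13 were lower in Mc and none higher, or 1 higher adjusted over the list alone. The basement membrane genes Col4a1 and Col4a2 measured 7.60 ± 2.07 against 106 ± 25.4 and 6.11 ± 3.15 against 128 ± 51.5 FPKM (camera adjusted p = 1.30e-06, and adjusted p = 0.365 with an estimated correlation). Of 31 Hox genes 7 were lower, and Hoxb9 measured 0.491 ± 0.167 FPKM against 40.6 ± 6.90. Wnt inhibitors split, with 3 of 18 higher (Shisa2 and Dkk3 among them) and 4 lower (Dkk2, Wif1, Sfrp1, Apcdd1). Dkk2 measured 0.519 ± 0.168 against 62.7 ± 2.54 FPKM. Wnt4 was lower among 16 Wnt ligands, and Apcdd1 and Tcf7 among 14 Wnt targets. The BMP antagonist gene Fst (1.57 ± 0.0162 against 58.6 ± 14.6) and Bmp4 were lower of 16, and Id3, which no left-out fit kept, of 6 BMP targets. In the Notch list Hey1 and Hes1 were higher and Heyl, Jag1 and Hey2 lower, of 17. The axon guidance list had 2 of 20 higher (Sema6a, Sema5a) and 5 lower, Sema3c at 0.793 ± 0.0703 against 62.1 ± 19.2 among them. The TGF-beta and activin list had 3 of 16 lower, the FGF ligand list 2 of 13 lower, the FGF response list Etv5 higher of 10, and the CDK inhibitor list Cdkn1c lower of 6. Genes of further cell types moved as well. Cdh1, the epithelial cadherin, measured 229.8 ± 8.27 FPKM in Mc against 6.79 ± 6.36 and was with Grhl2 the 2 of 18 keratinocyte genes higher, or 8 adjusted over the list alone and 9 with a replicate term (camera adjusted p = 0.000121, and adjusted p = 0.583 with an estimated correlation). Krt5 measured 109 ± 46.9 FPKM in Mc and 42.1 ± 44.4 in Sch. The keratinocyte list's mean level was -0.18 in Sch replicate 1 and -1.82 in Sch replicate 2, against 0.67 and -0.13 in Mc. Tyrobp and Fcer1g were higher and Laptm5 lower of 13 macrophage and leukocyte genes (camera adjusted p = 0.0182, and adjusted p = 0.506 with an estimated correlation). Dermal condensate genes had 8 of 22 lower and Hey1 higher, or 10 lower adjusted over the list alone (camera adjusted p = 0.00200, and adjusted p = 0.365 with an estimated correlation). The neuron list had Tubb3 higher and Syt1, Isl1 and Elavl4 lower of 7 (camera adjusted p = 0.0478, and adjusted p = 0.265 with an estimated correlation, 0.0630 with a replicate term). Fibroblast genes had 3 of 20 lower, Postn at 42.9 ± 11.1 against 865 ± 204, skeletal muscle genes 3 of 14 lower with Des at 0.330 ± 0.0717 against 28.2 ± 13.1, and mural cell genes 2 of 9 lower. Prox1 was higher among 17 endothelial genes, Ier3, which no left-out fit kept, was lower among 16 immediate early and stress genes, and Cdh3 was higher and Sox9 lower among 16 placode genes. None of the cell cycle, hedgehog, EDA and NF-kB, epidermal differentiation, mast cell or erythroid genes was called in the model without a replicate term. Adjusted over the list alone, 4 macrophage and leukocyte and 3 Notch genes were higher, 3 FGF ligand, 6 axon guidance and 2 CDK inhibitor genes and 0 immediate early and stress genes lower, and the lists without a count of their own did not change. With a replicate term 4 macrophage and leukocyte, 2 endothelial, 1 collagen, 1 Hox, 1 mural cell, 1 epidermal differentiation and 1 mast cell gene were higher and 2 CDK inhibitor genes lower. The median and mean log2 difference had opposite signs for Wnt inhibitors (0.09 and -0.39) and BMP ligands and antagonists (0.13 and -0.32), and the endothelial median was -0.22 with a mean just above 0. Of the 7 lists camera called, fry called all. It also called 11 that camera did not: FGF response upward, and neural crest transcription factor, mural cell, skeletal muscle, FGF ligand, BMP ligand and antagonist, BMP target, TGF-beta and activin, axon guidance, CDK inhibitor and Hox downward. Of 120 called genes that lead the ranking, were fixed beforehand or belong to a list, 89 kept the call whichever library was left out. Among the 31 that did not were, besides Erbb3, Id3 and Ier3, Elavl4, Fcer1g, Grhl2, Hes1, Hey1, Laptm5, Pax3, Tcf7 and Tubb3.

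DCSch, the fraction whose label joins DC and Sch, carried genes of both. Against Sch it was higher in 19 of 22 dermal condensate genes, and against DC in 10 of 15 Schwann cell genes. Sox2 measured 22.2 ± 4.04 FPKM in DC, 10.03 ± 1.08 in DCSch and 3.15 ± 0.595 in Sch, and Fabp7 47.0 ± 32.6, 443 ± 83.2 and 1267 ± 249. Against DC it was higher in 27 of 33 cell cycle genes, with Birc5 at 79.5 ± 4.71 FPKM. Adjusted over the list alone the counts were 20, 10 and 29. Dermal condensate genes were lower than in DC in 10 of 22, or 15 adjusted over the list alone, and Schwann cell genes lower than in Sch in 10 of 15 and higher in 1, or 12 and 1. Fibroblast genes were higher than in Sch in 13 of 20 and lower in 1, or 14 and 1 adjusted over the list alone, and none differed from DC. Neural crest transcription factors were higher than in DC in 6 of 10 and lower in 1, and higher than in Sch in 1 and lower in 7, or 8 adjusted over the list alone. Bmp4 measured 205 ± 16.0 FPKM in DCSch and 13.1 ± 2.66 in Sch, Ptch1 218 ± 47.2 and 16.8 ± 3.69, and Foxd3 29.3 ± 8.45 and 96.7 ± 25.1. DC and Sch themselves differed in 2727 genes, 1271 higher in DC and 1456 lower, with 20 of 22 dermal condensate and 11 of 20 fibroblast genes higher in DC and 12 of 15 Schwann cell genes lower. These 3 counts were the same adjusted over the list alone. DCSch was higher than DC in 625 genes and lower in 254, and higher than Sch in 750 and lower in 504. Without DCSch replicate 1 the 254 became 133. Over 1096 genes that set DC and Sch apart, DCSch lay at 0.597 of the way from Sch to DC (SD 0.0047 over the 2 libraries), and 96.6% of the genes lay between the DC and Sch levels. For the 494 genes higher in DC the position was 0.469, and for the 602 higher in Sch it was 0.665. DCSch was higher than both DC and Sch in 20 genes and lower than both in 2, Heyl and Anxa1. These comparisons took no account of how the DCSch cells were gated, which is not given in the sources used here.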

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

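The Pc with Epi count of 216 was 31 with a pseudocount of 0.1, of which 0 were higher in Pc, 97 on libraries rescaled to the same total, 368 with a replicate term, 353 with that term and a GC correction added after seeing the data, and 1 with only the 4 libraries compared. Leaving out single libraries gave 67 (Pc replicate 2), 79 (Epi replicate 2), 107 (Epi replicate 1) and 184 (Pc replicate 1), of which 8, 5, 9 and 7 were higher in Pc, with the lone library of a fraction taken to vary like the other groups. With only the 4 libraries compared, DC with Fb gave 1079 in place of 2172, DCSch with DC 2 in place of 879 and DCSch with Sch 662 in place of 1254. The single Pc signature gene became 0 with a pseudocount of 0.1 and without Epi replicate 2, 2 without Pc replicate 1, Pc replicate 2 or Epi replicate 1, 5 without a filter and with quantile normalization, 6 with a replicate term and 7 with a GC correction too. The 112 Epi signature genes became 1 with a pseudocount of 0.1, 70 with a filter of 5 FPKM, 41 rescaled to the same total, 44 without Pc replicate 2, 53 without Epi replicate 2, 56 without Epi replicate 1 and 118 without Sch replicate 1. The 215 Fb signature genes became 105 with a pseudocount of 0.1 and 333 with Neg left out, the 277 Sch genes 174 with a pseudocount of 0.1, and the 482 Neg genes 278 with a filter of 5 FPKM. The DCSch position of 0.597 was 0.617 at a log2 difference of at least 3, 0.634 rescaled to the same total, 0.579 by least squares, 0.558 without DC replicate 2 and 0.616 without Sch replicate 1. List tests called 17, 9 and 7 lists for Pc with Epi, DC with Fb and Mc with Sch, and 4, 2 and 1 with an estimated correlation. Genes lower in DCSch than in DC numbered 254, and 133 without DCSch replicate 1. Other totals moved by less than 1.5 times, and no gene changed sign among the called leading genes, fixed genes and list members of Pc with Epi, DC with Fb and Mc with Sch.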

Other observations

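Signalling genes differed in where their levels were highest, by level alone and without a test between epithelial and dermal fractions. Wnt10a measured 8.71 ± 5.16 FPKM in Pc and 6.43 ± 2.16 in Epi, against 0.539 ± 0.459 in Fb, and Wnt6 41.4 ± 12.2, 26.2 ± 14.3 and 2.37 ± 0.966. The Wnt ligand list was highest in Pc (1.31), while Wnt5a measured 105 ± 26.4 FPKM in Fb and 100.0 ± 15.5 in DC. Wnt inhibitors (0.61), FGF ligands (0.72), TGF-beta and activin (0.77), axon guidance (0.70) and collagen genes (1.44) were highest in Fb by list mean. Of their members, 4 of 18, 5 of 13, 4 of 16, 4 of 20 and 10 of 24 were highest in Fb. Rspo3, an amplifier of Wnt signals, measured 151 ± 24.4 FPKM in DC, where the FGF response (1.20), BMP ligand and antagonist (0.68) and CDK inhibitor lists (0.84) were highest. In these 3 lists, 5 of 10, 4 of 16 and 2 of 6 members were highest in DC. The mean of the hedgehog list was highest in DCSch (0.90), close to DC (0.87), though 0 of its 12 members were highest in DCSch. The EDA and NF-kB list was highest in Pc (0.94), as were 8 of its 13 members. Notch genes were highest in Neg (0.82), with the vessel genes Dll4 at 4.82 ± 2.56 FPKM and Notch4 at 4.24 ± 3.29. Sox18, also known from vessels, measured 31.8 ± 25.3 in Neg, and Flt1 10.9 ± 0.0799 in DC and 10.9 ± 0.321 in Neg.

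Genes higher in Pc than in Epi overlapped with genes lower in DC than in Fb: 10 were shared (2.02 by chance, Fisher's exact test p = 9.68e-06), Aurka, Cdc25c, Prc1 and Ube2c among them. These 4 lost the Pc with Epi call in every fit with a Pc or Epi library left out, so the overlap rests on unstable calls. The other pairings held 1 gene (1.35 by chance), 12 (11.9) and 14 (17.9).

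The tests of the replicates were chosen once the shared differences had been seen, with bounds set before they were run, and the test of GC content as the whole cause after the first result was seen. Hypothesis: an amplification bias tied to GC content could underlie part of what same-numbered libraries share, as the mean replicate difference followed GC content (Spearman's rho = 0.827). Taking the GC trend out lowered the median correlation between fractions from 0.483 to 0.242. This was a ratio of 0.501 against the bound of 0.5, so by its bound the test was undecided. The difference of replicate 1 from replicate 2 was positively correlated with GC content in each of the 8 fractions. Part of what same-numbered libraries share therefore went with GC content. Whether an amplification bias caused that part is undecided. The correlation that was left argues against the smooth trend removed as the whole cause, and other forms of GC bias stay open. Of 124 genes with a called replicate term 2.42% lie on X and Y, against 3.61% of the tested genes. This excludes sex as the cause of the whole pattern. A difference in sex composition stays undecided. The Y genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in replicate 2 in all 8 fractions. Ddx3y in DC measured 7.21 FPKM in replicate 1 and 18.5 in replicate 2. Yet Xist, made from the inactive X of females, was also higher in replicate 2 in all fractions but Pc and Mc. It measured 106 FPKM in DC replicate 1 and 267 in DC replicate 2, and 115 and 71.3 in Mc.

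The tests for pigment genes were chosen after the melanocyte result was seen, with bounds set before they were run. Hypothesis: melanocyte-lineage cells carried in Epi might explain the pigment genes lower in Pc. Of the 125 Mc signature genes with at least 10 FPKM in Mc, 76.8% were higher in Epi than in Pc, short of the 80% asked for. Among those 96 genes alone, the Epi excess was a median 2.64% of the Mc level (quartiles 1.72% to 4.11%). The genes that were not higher in Epi are left out of that median. Rescaling to the same total left 2 of 6 calls in place and quantile normalization 5, and the median log2 difference of the list stayed near its -1.48 at -1.49 and -1.37, so the lost calls are no evidence for scaling, and carried cells stay undecided. Counting cells that express Dct among sorted Epi cells would test the hypothesis of carried cells.

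The tests for Schwann cell genes were chosen after that result was seen, with bounds set before they were run. Hypothesis: Schwann cells carried in DC might explain its Schwann cell genes. Of the 187 Sch signature genes with at least 10 FPKM in Sch, 63.6% were higher in DC than in Fb. Among those 119 genes alone, the median excess was 3.34% of the Sch level. This does not settle the hypothesis. All 7 calls stayed with rescaling to the same total and with quantile normalization. The median log2 difference of all genes between DC and Fb was -0.003 as deposited, and 0 and 0.04 with these. Changes this small could hardly remove a call, so this test does not decide on scaling. For DCSch, the test and its bounds were chosen after the result was seen. Hypothesis: Fb-like cells in DCSch could account for part of its place short of both DC and Sch. The fitted Fb weight was 0.167 in replicate 1 and 0.1275 in replicate 2, and the 20 genes above both DC and Sch were all higher in Fb than in either. DC had weights of 0.347 and 0.438 and Sch of 0.294 and 0.293. All weights of a library together fell short of a whole, so Fb-like cells leave a part of the shortfall unexplained. Of the 128 Fb signature genes with at least 10 FPKM in Fb, 87 (68.0%) were higher in DCSch than in DC and Sch. Against it, 7 of the 20 were not above DCSch in Fb, some by little and others by more, such as Dkk1 (18.9 FPKM in DCSch and 11.8 in Fb), which a share of Fb-like cells alone does not explain.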
